A study of Drosophila melanogaster with 3 samples.

How the data were processed

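Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on whole Drosophila melanogaster prepupae of both sexes, the short stage between the end of larval life and the pupa. The flies carried a transgene in which green fluorescent protein (eGFP) is fused to the C-terminal end of CG44002, and chromatin was precipitated with an antibody against GFP. Chromatin was sheared by sonication to 200 to 800 bp, per the labels. The series holds 1 group of 3 biological replicates, numbered as separate biological replicates in the labels, and there is no contrast between groups. The labels name the tagged gene as CG44002 and the strain as CG34406. The reference gene table lists CG34406 as an older name shared by CG44002 and the neighbouring pseudogene CR44003.

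The authors deposited peak lists in the narrowPeak layout, called on 2 genome builds, dm6 and dm3. For each build there is 1 list of 30000 peaks per replicate, 1 list of 30000 peaks from the pooled replicates, and 1 list thresholded by the irreproducible discovery rate (IDR), a measure of how well peak ranks repeat between replicates. Per the file inventory deposited with each library, each list was made from an alignment and 1 control file. The control itself was not analysed here. The aligner, the peak caller and the IDR threshold are not given in the sources used here. Each peak carries the authors' signal value, a number above 0 whose scale is not stated, and it was used only to rank or describe peaks within 1 list. Each peak also carries a −log10 q-value per the deposited column order, which was the same for every peak of the IDR list and was not used to rank peaks. All 7089 peaks of the dm6 IDR list were the 7089 highest-signal peaks of the pooled list, and the same held for the 6964 peaks of the dm3 list. The IDR list is therefore a pooled list with no error of its own. Values with an SD come from the 7089 highest-signal peaks of each replicate list, called the top N below. Read depth is unknown, and 0 columns of other samples were present.

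Coordinates are dm6 and 1-based. Peak ends lay within the arm lengths of the release 6 sequence, and genes were taken from Ensembl release 115 (BDGP 6.54), leaving out transposable elements, which left 18164 genes on 6 arms, of which 13945 code for protein. Each summit was placed in the first class that applied, in the order promoter (within 500 bp of any annotated start), 5′ UTR, 3′ UTR, coding exon, other exon, intron and intergenic. Shares were compared by rank, two-sided, with 1000 random sets holding the same number of positions per arm. Overlap between lists counted a summit lying inside a peak of the other list and was compared, one-sided, with 1000 circular shifts. A gene was called bound when an IDR summit lay within 500 bp of any of its starts. Fisher's exact test, two-sided, was used for the X chromosome, for divergent promoters (another gene starting on the other strand within 1 kb upstream) and for 25 gene lists, with Benjamini-Hochberg adjustment over the 25 lists and a threshold of 0.05. Median signals were compared with a permutation test of 100000 resamples. Intervals on shares are 95% exact binomial intervals and cover counting error only, and a count of 0 was given the limit that 3 counts would set. Values given without a replicate come from the IDR peaks whose summit lay in the top N of both other replicates. The pooled list was not called again, so the replicate left out still contributed to the position and signal of these peaks.

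A set of 29 consensus strings was sought on both strands in the 200 bp around each summit and in 200 bp centred 500 bp away on a randomly drawn side, and compared with the exact McNemar test with adjustment over the 29. Strings of 7 bases were chosen in 100 bp windows on arms 2L and 2R and tested on 3L, 3R and X. Gene lists, strings, tests and most alternatives were fixed before the data were examined. Alternatives chosen after seeing the data were the comparison with dinucleotide-shuffled summit sequences, random positions matched on AT content, gene lists matched on number of starts and divergent arrangement, the count without the histone list, and other distances around the tagged gene. The genes named are those next to the 25 highest-signal IDR peaks that lay in the top N of all 3 replicates within 1 kb of a start, up to 4 bound members of each list by signal, CG44002 and CG34406, every arm and every string. A gene that this rule names is not reported here. Other genes named were chosen after their values were seen, and the text says so.

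The scripts were tested on simulated data placed on the real genome. With random summits the promoter share gave a randomisation p of 0.859, and with summits moved into promoters the expected 39.4% was recovered as 39.3%. In the gene list test on 13945 genes, all 5 planted lists and 0 of 200 unchanged lists were called. A planted consensus string was called with 0 of 28 others, a planted 7-base string ranked 1, and 79.8% overlap was recovered where 79.5% of peaks had been kept. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.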

Results

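CG44002-eGFP occupancy was mapped in 3 biological replicates of whole prepupae. The IDR list held 7089 peaks with a median width of 430 bp, covering 2.5 Mb. Read depth is unknown from peak lists, so the number of replicates and of peaks sets the precision of the values that follow.

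The strongest peaks were found at the same places in all 3 replicates. The peak 91 bp upstream of CG14100 on 3L (19590421 to 19590826) ranked 4 in replicate 1, 3 in replicate 2 and 2 in replicate 3, and the peak 43 bp upstream of Ugalt, a UDP-galactose transporter, on X (2703676 to 2704091) ranked 5, 4 and 3. Of the IDR peaks, 85.6% ± 2.49 (SD, n = 3) lay in the top N of a replicate, against 1.93% after circular shifts (permutation p = 0.000999, one-sided, the smallest possible). In all, 4781 peaks (67.4%) lay in the top N of all 3 replicates, 1588 in that of 2, 679 in that of 1 and 41 in none. Between replicates, 77.7% of top N peaks were shared on average over the 6 ordered pairs, from 75.4% to 80.2%, against 1.93% by chance (permutation p = 0.000999, the smallest possible). Across peaks, which are not independent replicates, ranks correlated with Spearman's rho of 0.81 for replicates 1 and 2, 0.79 for 1 and 3 and 0.76 for 2 and 3. The IDR list was itself made from these replicates, so its overlap with them is not independent.

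Peaks were spread over the large arms and were sparse on chromosome 4, the small and largely heterochromatic chromosome. There were 54.1 IDR peaks per Mb on 2L, 47.9 on 2R, 57.6 on 3L, 50.5 on 3R and 57.7 on X, but 9 peaks on chromosome 4, or 6.68 per Mb. In the replicates chromosome 4 held 10.9 ± 2.27 peaks per Mb (SD, n = 3) and X 56.9 ± 2.98. Promoters of X-linked coding genes were bound at 443 of 2196 genes (20.2%) and autosomal ones at 2276 of 11669 (19.5%), a difference that did not pass the test (odds ratio 1.04, Fisher's exact p = 0.464).

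Summits gathered at promoters and were nearly missing from coding exons. Promoters held 2565 summits, 36.2% (95% interval 35.1% to 37.3%), against 13.6% of random positions, and 38.1%, 37.3% and 38.8% in replicates 1, 2 and 3. Coding exons held 9 summits, 0.127% (95% interval 0.0581% to 0.241%), against 13.1% at random, and 0.136% ± 0.029 (SD, n = 3) in the replicates. The 3′ UTRs held 0.691% against 5.06%, and intergenic DNA 18.3% against 27.2%. Introns held 3050 summits, the largest class, at 43.0% against 39.5%. The 2-sided randomisation p was 0.002 for promoters, introns, intergenic DNA, 3′ UTRs and coding exons, the smallest that 1000 draws can give. For 5′ UTRs (0.578% against 0.783%) it was 0.034, and for other exons (1.07% against 0.809%) 0.028. The 5′ UTR deficit was lost against random positions matched on AT content, of which 0.579% fell in 5′ UTRs (0.353% to 0.846% over 100 draws). The intron excess was also lost against these matched positions, of which 44.1% fell in introns (permutation p = 0.099), and with a 1000 bp promoter window (35.9% against 36.2%, permutation p = 0.563). Coding exons held 3.77% of the AT-matched positions on average, well below 13.1% of unmatched positions but above the 0.127% of summits. With a 200 bp window promoters held 22.2% of summits against 6.17% at random.

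**Figure D1:**
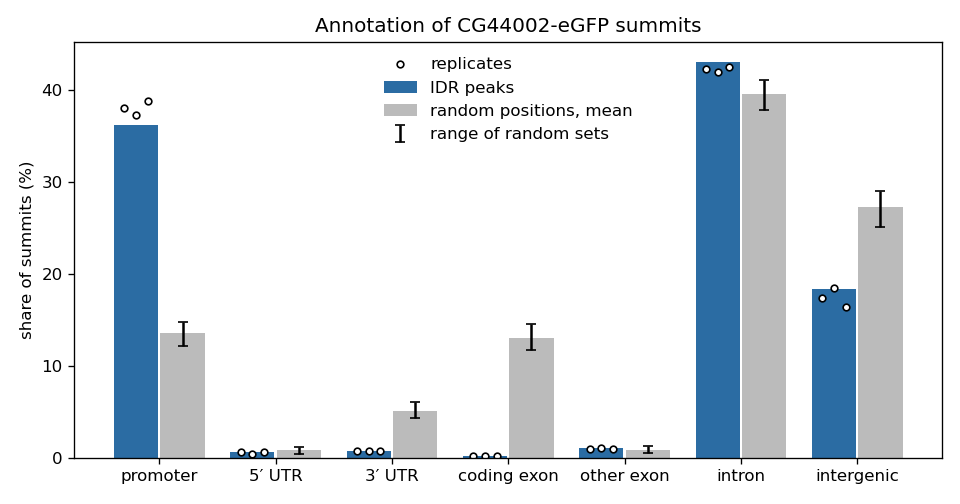
Share of summits (%) in each annotation class for the 7089 IDR peaks (blue bars), the top N of each replicate (points) and 1000 random sets (grey bars, mean, with lines for their range). Promoters hold 36.2% of summits against 13.6% at random, and coding exons 0.127% against 13.1%.

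Within promoters the summits lay mostly just upstream of the start. Of the promoter summits, 2010 lay upstream of the nearest start and 551 downstream, or 78.5% upstream, with a median of -127 bp and quartiles of -227 and -22 bp. The upstream share was 77.9%, 81.0% and 70.7% in replicates 1, 2 and 3. A summit between divergent starts lies upstream of whichever start is nearest, so part of this share follows from the measure. No random positions were drawn for it. Divergent promoters were bound more often, at 1551 of 5057 coding genes (30.7%) against 1173 of 8888 (13.2%), with an odds ratio of 2.91 (Fisher's exact p = 1.92e-133), and of 2.92 ± 0.312 (SD, n = 3) in the replicates. A summit between divergent starts counted for both genes. The genes are therefore not independent, which can raise the odds ratio and make the p too small. The test was not run with each summit given to its nearest start only. In all, 2724 of 13945 coding genes (19.5%) and 334 of 4219 other genes (7.92%) were bound.

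**Figure D2:**
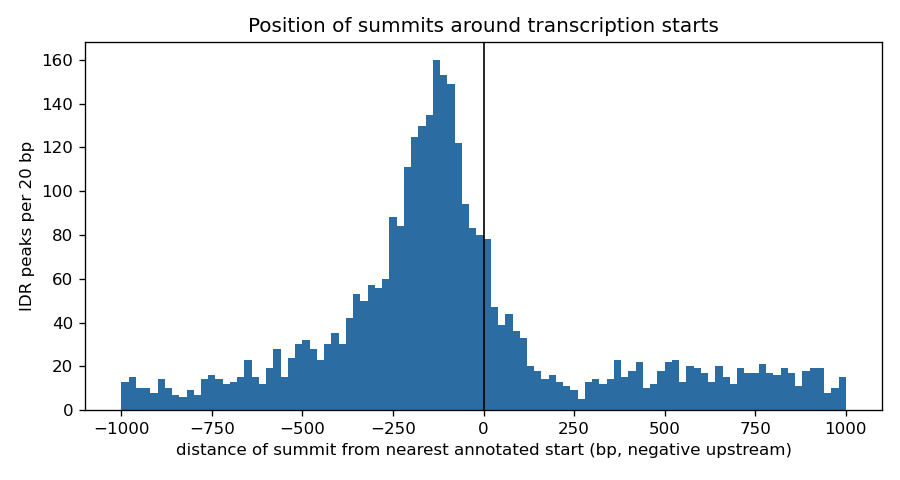
Number of IDR peaks per 20 bp by distance of the summit from the nearest annotated start (bp, negative upstream). The median of summits within 500 bp is -127 bp.

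Promoter peaks were stronger than other peaks within the IDR list. The median of the authors' signal value was 174 at the 2565 promoter summits and 151 at the 4524 others, a difference of 23.7 (permutation p = 2e-05, the smallest possible). In the replicates' own lists the difference was 6.34, 6.45 and 2.55 for replicates 1, 2 and 3, above 0 in each. The scale of the signal is not stated, so these sizes cannot be set against each other or against the pooled value. Within the IDR list the difference was 39.99 among peaks supported by replicates 2 and 3, without replicate 1, 36.3 among peaks in the top N of all 3 replicates, 35.9 in the stronger part of the list and 14.7 with a 200 bp promoter window. When the list was divided by signal into 10 groups, promoters made up 52.4% of the strongest group and 30.3% of the weakest. The 25 named peaks were chosen to lie within 1 kb of a start, so their place in promoters adds nothing to this. The IDR peaks of ranks 1, 2 and 3 lay farther from any start, in introns and intergenic DNA, and are not among the named peaks. Among the 25 named peaks, those at PNPase (mitochondrial polynucleotide phosphorylase), Chro (the chromatin protein Chromator), mRpL41, Fkbp14, Hsp27 (a small heat shock protein), Gapdh2 (a glycolytic enzyme), larp, gish, Art3, CenG1A, Tcs5, CG18549, CG1888, CG9147, CG31145, CG5611, CG18428 and the noncoding RNA lncRNA:CR31044 lay in promoters. The summit at Hsp27 lay 143 bp upstream of its start on 3L (9383920) and that at Gapdh2 167 bp upstream on X (15867978). Several lay within 500 bp of the start of a second gene, such as CenG1A with mRpS23, Chro with Ssl1, Art3 with mRpS10 and CG18428 with eIF4EHP. Those at Lk6, a protein kinase (969 bp upstream of the nearest start), HmgZ (599 bp upstream) and CG4496 (560 bp upstream) were in introns, and those at lncRNA:CR46035 and lncRNA:CR44619 in noncoding exons.

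Genes of the cytosolic ribosome were bound far more often than other genes, and chemosensory and cuticle genes far less. Of 93 cytosolic ribosomal protein genes, 67 (72.0%, 95% interval 61.8% to 80.9%) were bound, against 19.2% of other coding genes (odds ratio 10.9, Fisher's exact test, adjusted p = 1.35e-26), and 71.0% ± 3.23 (SD, n = 3) in the replicates. The odds ratio was 18.3 with a 200 bp window. Among the strongest of their peaks were those at RpS27 (rank 560), RpL7 (566) and RpL32 (790). Ecdysone response genes, which answer the moulting hormone that starts metamorphosis, were bound at 12 of 24 (50%, odds ratio 4.13, Fisher's exact test, adjusted p = 0.00388), and at 50% ± 4.2 (SD, n = 3) in the replicates. Among them were Ldh (lactate dehydrogenase, rank 160), Eip75B (a nuclear receptor, rank 308), Hr3 (rank 1096) and vri (rank 1684). This call was lost with a 200 bp window (odds ratio 1.81, Fisher's exact test, adjusted p = 0.367) and against lists matched on number of starts and divergent arrangement (permutation test, adjusted p = 0.427).

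Of 122 coding cuticle protein genes none was bound, which allows a share of up to 2.46% (Fisher's exact test, adjusted p = 4.15e-11). The only bound member of that list, TwdlU, is annotated as a pseudogene and was not counted. Chemoreceptor and odorant-binding genes were bound at 4 of 230 (1.74%, odds ratio 0.0715, Fisher's exact test, adjusted p = 1.45e-15), and these were Obp83g, Obp99b, Gr77a and Ir94f. This list, like that of egg shell and yolk genes, had been fixed beforehand as a comparison set with low binding, so its low share was anticipated. Histone genes were bound at 2 of 115 (Fisher's exact test, adjusted p = 5.54e-08), and both, His2Av and His3.3B, encode variants from outside the tandem histone cluster. The clustered copies are near-identical, and how the authors placed reads shared between copies is not given in the sources used here, so the value for this list is uncertain.

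The remaining 20 lists did not pass the threshold. Chromatin regulators were bound at 12 of 33 genes (adjusted p = 0.069 by Fisher's exact test), with ph-p, a Polycomb gene, at rank 53, brm, the ATPase of a remodelling complex, at rank 108, the insulator gene Cp190 at 235 and E(z) at 298. This list passed with a 200 bp window (odds ratio 2.99, Fisher's exact test, adjusted p = 0.0261) and with a 1000 bp window (odds ratio 2.44, Fisher's exact test, adjusted p = 0.0404), and not against matched lists (permutation test, adjusted p = 0.494). Cell death and autophagy genes were bound at 11 of 31 (adjusted p = 0.086 by Fisher's exact test), with hid at rank 228, Atg2 at 337, Atg17 at 718 and Atg18a at 1249. Mitochondrial ribosomal protein genes were bound at 21 of 73, with mRpL41 at rank 14, mRpS23 at 15, mRpS10 at 23 and mRpL23 at 52. The summits at mRpS23 and mRpS10 lay nearest to the starts of CenG1A and Art3. For this list the odds ratio was 1.67, and 0.729 when each summit went to its nearest start only, neither past the threshold. Lists of other abundant machinery did not pass, with 16 of 86 for oxidative phosphorylation (ND-ASHI, ND-MWFE, ND-42 and ND-51), 8 of 48 for the proteasome (Rpn3, Rpn5, Prosalpha4 and Rpn8) and 13 of 51 for translation factors (eIF4EHP, eIF6, eEF1gamma and eIF1). None of the 22 glue and 71E secretion genes (adjusted p = 0.056 by Fisher's exact test, a share of up to 13.6%) and none of the 20 antimicrobial peptide genes (adjusted p = 0.069, a share of up to 15%) was bound. The tRNA genes were bound at 14 of 295, among them tRNA:Tyr-GTA-1-8, and small nuclear and nucleolar RNA genes at 13 of 289, among them snoRNA:U49:66Da. The last lies within a cytosolic ribosomal protein gene called by the same summit (rank 852). The summit of eIF1 (rank 1223) was likewise shared with a cytosolic ribosomal protein gene, so some summits count in more than 1 list. With a 1000 bp window the glue, antimicrobial peptide and tRNA lists passed as bound less often (Fisher's exact test, adjusted p = 0.0184, 0.0255 and 0.0427). When each summit went to its nearest start only, the tRNA and small RNA lists did so (Fisher's exact test, adjusted p = 0.0409 and 6.45e-05), as did the small RNA list with a 200 bp window (Fisher's exact test, adjusted p = 0.0261) and the glue list against matched lists (permutation test, adjusted p = 0.049).

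Counts for developmental lists were 5 of 37 for disc patterning (aos, Dll, so and salr), 5 of 21 for Notch and bristle genes (E(spl)mdelta-HLH, E(spl)m3-HLH, numb and E(spl)m7-HLH), 1 of 8 for Hox genes (Dfd), 3 of 19 for neuronal genes (elav, Syx1A and futsch), 5 of 23 for muscle genes (Tm1, sls, Mef2 and Act87E) and 4 of 12 for fat body genes (bmm, Adh, FASN1 and Lsd-1). Ecdysteroid synthesis and transport genes were bound at 3 of 12 (Oatp74D, shd and mld), heat shock genes at 6 of 21 (Hsp27, Hsp83, Hsp26 and Hsp22), and cell cycle genes at 8 of 32 (Dp, CycE, Mcm2 and dap). The egg shell and yolk list had 1 of 19 bound, Cp190, which the symbol pattern for chorion genes takes in although it encodes an insulator protein. At an unadjusted p below 0.05, 11 lists passed.

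**Figure D3:**
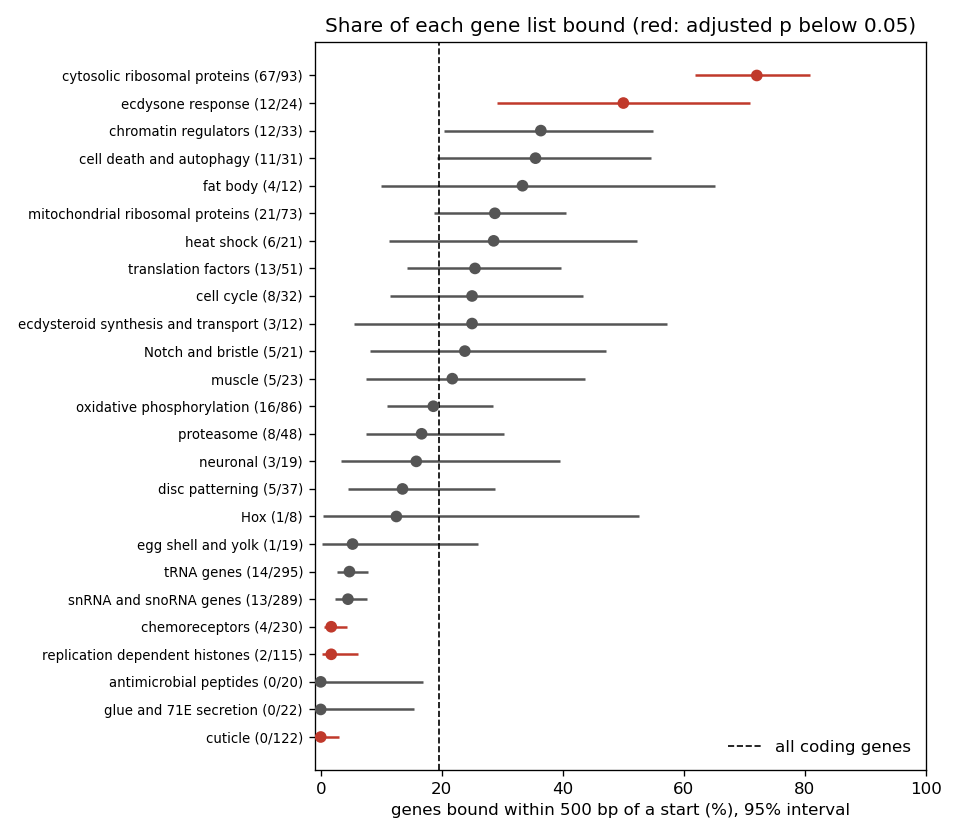
Percentage of each gene list bound within 500 bp of a start, with 95% exact binomial intervals and the numbers bound and in the list. The dashed line is the share of all coding genes, 19.5%, and the tRNA and small RNA lists were tested against other noncoding genes. Cytosolic ribosomal protein genes stand at 72.0%.

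The sequence at summits was rich in A and T. In the 100 bp around the summit 67.8% of bases were A or T, and 67.2% ± 0.85 (SD, n = 3) in the replicates, against 56.7% and 55.7% centred 200 bp to the left and right and 57.8% over the 6 arms. The share was 71.3% in the strongest of the 10 signal groups and 64.3% in the weakest. Of 29 consensus strings, 9 were more frequent at summits than in flanks and 13 less frequent. Among the strings of core promoters, the DRE string TATCGATA was found at 1.71% of summits and 0.409% of flanks (exact McNemar test, adjusted p = 3.77e-14), the M1BP string at 0.592% and 0.169% (adjusted p = 9.44e-05 by the exact McNemar test), the Ohler 7 string at 3.98% and 2.31%, and the TATA box at 8.93% and 4.09%. Among the 4524 summits outside promoters the DRE (0.332% and 0.199%, exact McNemar test, adjusted p = 0.357), M1BP (0.155% and 0.155%) and Ohler 7 strings (2.25% and 2.23%) did not pass, and the TATA box did (8.73% and 4.09%). The others were the strings for Mef2 (13.2% and 5.70%), Abd-B (34.4% and 24.4%), homeodomains (18.6% and 11.1%), Su(Hw) (1.90% and 1.03%) and a run of A (19.5% and 12.4%). The TATA, Abd-B and homeodomain strings were not more frequent than in dinucleotide-shuffled copies of the summits (8.93%, 35.0% and 20.4% of copies). The homeodomain string was less frequent than in copies (exact McNemar test, adjusted p = 0.0121). Less frequent at summits were CA repeats (3.65% and 6.79%), and the strings for Hes and Max proteins (1.38% and 2.69%), Runt (5.53% and 8.65%), the E-box (6.80% and 9.17%), Ftz-F1 (0.324% and 1.03%), NRF1 and Ewg (0.127% and 0.423%), C/EBP, Scalloped, Pho, AP-1, Zelda, Hr3 and the initiator. Of these 13, the Hes and Max and the C/EBP strings were also less frequent than in shuffled copies (2.26% and 1.58% of copies), while CA repeats and the E-box were more frequent than there (0.592% and 2.82% of copies). The call was lost for Hr3 without replicate 1 and without replicate 3 (exact McNemar test, adjusted p = 0.0962 and 0.129), for Zelda without replicate 2 and without replicate 3 (exact McNemar test, adjusted p = 0.134 and 0.0724), and for C/EBP without replicate 3 (exact McNemar test, adjusted p = 0.0576). The initiator and Hr3 calls were also lost in the stronger part of the list (adjusted p = 0.234 and 0.0956 by the exact McNemar test) and among peaks in the top N of all 3 replicates (adjusted p = 0.0521 and 0.107 by the exact McNemar test), and those for Zelda, Hr3 and NRF1 in windows of 100 bp. At promoter summits the strings for Pho (7.56% and 7.56%), the initiator (16.5% and 17.0%), the E-box (9.40% and 10.5%), Hr3, C/EBP, AP-1 and Zelda did not pass, and outside promoters those for C/EBP, AP-1, Zelda and NRF1 did not. Over all summits, the 7 that did not pass in either direction were the strings for GAGA factor and CLAMP (4.09% and 4.54%), the ecdysone response element (0.0282% and 0.0846%), CTCF, GATA factors, heat shock factor, CRE and BEAF. The GAGA string was more frequent at promoter summits (5.65% and 4.21%, exact McNemar test, adjusted p = 0.0371) and less frequent at summits outside promoters (3.21% and 4.73%, exact McNemar test, adjusted p = 0.000447), a difference that was not itself tested. It was also less frequent without replicate 1 (3.30% and 4.44%) and without replicate 3 (3.19% and 4.27%), in the stronger part of the list (3.36% and 4.63%), among peaks in the top N of all 3 replicates (3.33% and 4.31%) and in windows of 100 bp (1.54% and 2.47%), but more frequent than in shuffled copies (0.987% of copies). The GATA string was more frequent in windows of 100 bp (1.74% and 1.27%, exact McNemar test, adjusted p = 0.0376). The strings for CTCF, heat shock factor and BEAF were more frequent than in shuffled copies (0.790% against 0.169%, 0.395% against 0.113% and 0.141% against 0.0141% of copies; exact McNemar test, adjusted p = 2.57e-07, 0.00267 and 0.0227).

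**Figure D4:**
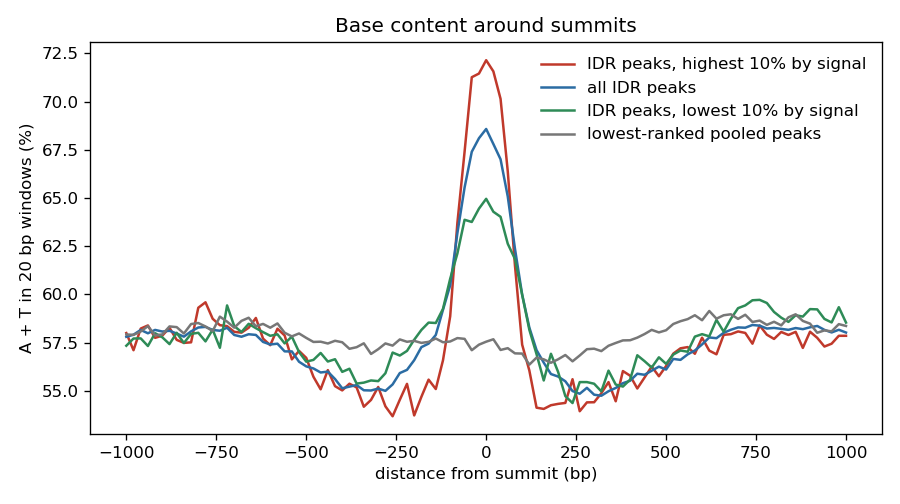
Share of A and T (%) in 20 bp windows by distance from the summit (bp) for all IDR peaks, the 10% with the highest and the 10% with the lowest signal, and the 5000 lowest-ranked pooled peaks. The axis does not start at 0. In 100 bp windows the summit stands 11.6 percentage points above its surroundings for all IDR peaks and 0.27 points for the lowest-ranked pooled peaks.

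All 10 of the 7-base strings chosen on 2L and 2R consisted of A and T alone, and all 10 passed on 3L, 3R and X. TTAAAAA was found at 16.4% of 4597 summits and 5.81% of flanks (exact McNemar test, adjusted p = 1.09e-58), and TAAAATA at 14.1% and 4.24% (exact McNemar test, adjusted p = 1.11e-60).

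The tagged gene itself was not bound at its start. CG44002 is also listed under the older name CG34406, which it shares with the pseudogene CR44003. CG44002 lies on 2L from 3169820 to 3171092, and no IDR summit lay within 500 bp of its start. Within 20 kb there were 4 IDR peaks, of ranks 2022, 2625, 3367 and 5890. The nearest, with its summit at 3172957, lay 1865 bp upstream of CG44002, within 500 bp of the starts of the pseudogene CR44003 (3171035 to 3172799) and of tRNA:Ser-AGA-2-4 (3173003 to 3173084). As many or more peaks lay within 20 kb of 34.5% of coding genes, for which the median was 2. This share depended on the distance. Within 10 kb there was 1 IDR peak (66.3% of coding genes with as many or more, median 1). Within 50 kb there were 4 (73.4%, median 6).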

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

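Peaks outside the 6 arms were found in the dm3 pooled list, which no comparison used. It holds 51 of its 30000 peaks on heterochromatic or unplaced sequence, and was flagged because this is more than 3. The dm6 lists hold 0 peaks outside the 6 arms. The builds may divide the genome differently between arms and other sequence, so these counts cannot be set against each other. By sequence there were 19 on 3LHet, 12 on 2RHet, 7 on XHet, 7 on U, 3 on 3RHet, 2 on 2LHet and 1 on Uextra. The dm3 IDR list holds 3 such peaks and the dm3 lists of replicates 1, 2 and 3 hold 40, 97 and 54, and these lists were used only as alternatives for the number of peaks and the overlap of replicates.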

How the results depend on the processing

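Of 144 alternative values over 19 results, 134 kept their direction and side of the threshold, or a count within 1.5 times. The promoter, intergenic and divergent results, the signal difference, the overlap of replicates, and the counts of enriched and 7-base strings did so under each alternative run, though 12 strings were enriched over shuffled copies and 6 of the 9 were among them. No alternative for the divergent result kept a summit from counting for both genes. At summits outside promoters the count of enriched strings was 6, without the DRE, M1BP and Ohler 7 strings. The pooled list was not called again without a replicate. Its peaks supported by both other replicates, taken for each replicate in turn, gave a promoter share of 35.9% to 36.8%, with 2 lists more and 3 less often bound. For the X chromosome, which passed no threshold, the odds ratio fell below 1 with the stronger peaks alone (0.974) and with a 200 bp window (0.889), and the cause was not tested. The intron share turned from above to below random with a 1000 bp window (35.9%), which moves intronic summits into the promoter class, and against positions matched on AT content (43.0% against 44.1%), where the cause was not tested. Lists bound less often numbered 6 with a 1000 bp window, which added the glue, antimicrobial peptide and tRNA lists, and 5 when each summit went to its nearest start only, which added the tRNA and small RNA lists, and lists bound more often numbered 1 against matched lists, where the ecdysone list did not pass. For these counts the cause was not tested. Around CG44002, 66.3% of coding genes had as many peaks within 10 kb and 73.4% within 50 kb. The matched, shuffled, histone and distance alternatives were chosen after seeing the data. Most alternatives reused the same pooled list or parts of it, so they are not independent. Some could hardly come out otherwise. All 7089 peaks lie on the arms, and the overlap of replicates could not be marked as reversed. The count of 134 therefore does not measure robustness. Read depth is unknown, so its effect on weak peaks could not be measured.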

Other observations

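The genes with the most IDR summits in their bodies, chosen after their values were seen, were long. kirre on X, a cell adhesion gene, held 27 over 394 kb, sbb on 2R 25 over 79.1 kb, CG1677 on X 23 over 125 kb, shn on 2R, a zinc-finger gene of the Dpp pathway, 22 over 58.3 kb, and Tet on 3L 21 over 93.0 kb. Among these genes with many summits, Mnt on X stood higher per length, with 14 summits over 29.9 kb. This is 4.69 per 10 kb, against 0.685 for kirre. No count expected from gene length was computed. Of 57 gene families formed from shared symbol prefixes, each with at least 10 coding members, 0 passed Fisher's exact test with Benjamini-Hochberg adjustment. The lowest p values were for ppk, ion channel genes, with 0 of 29 bound (adjusted p = 0.166 by Fisher's exact test) and for Cyp, cytochrome P450 genes, with 7 of 85 (adjusted p = 0.166 by Fisher's exact test).

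The tests of library base composition, of consensus strings against shuffled sequence, of other abundant gene lists, and of CACTG strings against shuffled sequence were chosen only after the result was seen. The comparisons with AT-matched positions and with matched gene lists, used below, were also alternatives chosen after seeing the data. No biological explanation was tested, since there is 1 group, and neither the control nor a map of open chromatin was analysed here. Unspecific signal at open chromatin, at promoters or elsewhere, therefore stays open for each pattern below. The AT excess over positions 200 bp away was 13.1 percentage points at the 4524 summits outside promoters and 8.91 at the 2565 promoter summits. These values argue against signal at promoters as the whole cause of AT-rich summits.

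Summits were AT-rich, and base composition of the libraries cannot be told apart from binding to AT-rich DNA here. The AT excess of the 5000 lowest-ranked pooled peaks was 0.0237 of that in the IDR list (95% bootstrap interval -0.0013 to 0.0501), but coverage biased towards AT would also give weak peaks a small excess, and AT content rose with signal within the IDR list (Spearman's rho 0.22 across peaks). Whether AT content alone is enough to make a peak stays open too, since 1.59% of the 222001 genome windows at least as AT-rich as the median summit lay near an IDR summit and the number of summits allows 6.39% at most. Of the 9 strings more frequent than in flanks, 6 were also more frequent than in shuffled copies of the summits. This alone cannot exclude base composition, since shuffling also breaks up runs and repeats, and no shuffled flanks were compared. CA repeats were 6.17 times as frequent at summits as in copies, though less frequent than in flanks. The DRE, M1BP and Ohler 7 strings did not pass outside promoters, where summits were 68.4% A or T, against 66.7% at promoters. For the Ohler 7 string, whose shares at summits and flanks outside promoters were nearly equal, this argues against AT content as the whole cause. The DRE and M1BP strings were rare outside promoters, so for them not passing decides little. Base composition other than AT content was not compared between the sets of summits. For Mef2, 1 of the 6, the ratio fell from 2.32 against flanks to 1.17 against copies. Base composition stays open for the DRE, M1BP, Mef2, Su(Hw), TATA, Abd-B and homeodomain strings and the run of A. For the Ohler 7 string, base composition other than AT content stays open. The homeodomain string was less frequent than in copies.

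Summits were nearly missing from coding exons. AT-matched random positions fell in coding exons in 3.77% of cases on average and in at least 3.40% in each of 100 draws. Summits did so in 0.127%, which argues against AT content as the whole cause. The share of unmatched random positions was 13.1%, so matching on AT content removed much of the gap.

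Ribosomal protein genes were bound more often than other genes. Among 10000 lists matched on starts and divergent arrangement the highest share bound was 48.4%, against 72.0%, which argues against these features as the whole cause. Unspecific signal drawn by high transcription cannot be told apart from specific binding, since transcription was not measured. Oxidative phosphorylation, proteasome and translation factor genes together had an odds ratio of 1.03 (95% interval 0.697 to 1.49), but these lists had already been seen not to pass and their transcription relative to ribosomal protein genes is unknown here. The ecdysone response list is different, since 92.3% of its matched lists had a lower share, and the number of starts and divergent neighbours may account for its excess.

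Strings with the core CACTG were noticed over shuffled copies with all arms in view, so the values below describe these summits and decide nothing about base content. All 10 strings of 7 bases with this core chosen on 2L and 2R passed on 3L, 3R and X against shuffled summits, and 6 passed against flanks. The core was 1.86 times as frequent at summits as in shuffled copies, above 100% of the 59 other strings of the same base content (median 0.93). Against flanks the ratio was 1.07, and 3 of those strings had a higher one.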
